A study of Mus musculus with 42 samples.

How the data were processed

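The deposited tables hold raw counts of reads per gene, which the authors made before deposit; per the submitters' processing notes reads were aligned with STAR 2.5.2b and assigned to genes with featureCounts 1.5.1 on genome build GRCh38. That is a human build while the gene symbols are those of mouse, so no coordinates are given, and annotation release M21 on build GRCm38 served only to match names and to find neighbouring genes. Sequencing was on a HiSeq 1000 per the labels. The whole-brain table has 24421 rows for 8 samples (95.7% of symbols matched) and the other, for cortex and hippocampus, has 53546 for 34 samples (93.5% matched); 0 columns were left without a sample. The whole-brain table holds no mitochondrially encoded genes. Every column was whole numbers with no sign of prior scaling.

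Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Whole brain, cortex, hippocampus and the region comparison were each fitted on their own because age, sex-linked genes and table rows differ between whole brain and the rest. Genes passed filterByExpr with a minimum count of 10, libraries were scaled by TMM, and edgeR quasi-likelihood tests with robust dispersions gave p-values, adjusted by Benjamini-Hochberg over all genes tested, two-sided, with adjusted p under 0.05 as the threshold. Each fit held all groups of its tissue, and interactions were tested as contrasts of contrasts. Folds are 2 to the power of the fitted log2 difference, and levels are mean CPM with SD over libraries. The prior count of 2 was used for log2 CPM values and not for these folds. Very large folds from levels near 0 therefore rest on few counts in the lower group. Where all libraries of a group had no counts, the fold is a lower bound against a floor of 3 counts per library. DESeq2 1.42.0 was the other tool.

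Gene lists were fixed before the values were examined: homeostatic microglia, disease-associated microglia, type I interferon response, MHC class I and class II presentation, nuclear subunits of respiratory complexes I to V, mitochondrial DNA-encoded genes, TCA cycle and pyruvate dehydrogenase, glycolysis, acetate uptake, sensing and acetyl-CoA use, histone acetyltransferases and deacetylases, phagocytosis and lysosome, inflammatory cytokines and NF-kB targets, immediate-early and dissociation stress, proliferation, cholesterol synthesis, cholesterol export and LXR targets, circadian clock, unfolded protein and heat shock response, ribosomal proteins, Y-linked, X inactivation, 5xFAD transgene homologues, and markers of other brain and blood cells. Some genes sit in several lists (Apoe, Axl, Ctsb, Ctsd, Sdha, B2m). camera compared each list with all other genes at a preset correlation of 0.01, and again with the correlation estimated from the data; fry tested lists on their own. List levels are means of log2(CPM + 1).

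Genes were named by a rule set before the values were examined. Up to 8 per direction with the largest fold among genes called at a mean of at least 5 CPM in a group, predicted gene models left out, or the 3 with the smallest p per direction where none passed. Up to 4 with the smallest p from each list described. And always, among others, Sdha, Sdhb, Sdhc, Sdhd, Acss1, Acss2, Apoe, Trem2, Clec7a, Cst7, Itgax, P2ry12, Tmem119, App, Thy1, Xist and Ddx3y. Some genes the rule selects are left out of the report.

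Replicates are separate animals per the labels, and p-values measure only the spread between these samples. In 61 pairs of libraries within groups, chi-square per degree of freedom of the counts was 10.09 to 60.25, above the value of 1 for sampling alone. Whole-brain SPF and GF share replicate numbers that name different mice. Cortex and hippocampus of 11 wild-type animals carry the same animal numbers, and the region test used the animal as a block. Residuals of the same animal in both regions had r from 0.029 to 0.343 across genes, over 0.1 in 9 of 11. Fits were also tested on simulated data with 100 genes changed. At log2 1 and log2 2 the share recovered was 78% and 93% in whole brain, 69% and 84% in cortex GF against SPF, 71% and 96% in cortex acetate against GF, 40% and 72% in wild-type hippocampus GF against SPF, 50% and 79% in 5xFAD acetate against GF, 51% and 72% in SPF 5xFAD against wild type, 28% and 55% in the 5xFAD interaction, and 72% and 88% between regions. False calls made up 0.8% to 7% of all calls.

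Alternatives were DESeq2, RLE size factors, no filter, a filter at a mean of at least 5 CPM, a fit of only the groups compared, each replicate left out, a replicate block in whole brain, the mean level of Y-linked genes as a covariate in cortex and hippocampus, no block between regions, camera with an estimated correlation and fry. Chosen after seeing the data were fits without SPF2152, without SPF2152, GFA518 and GF530, without the shallow libraries, and of the regions without animals GFA518 and GF530. Isoforms, splicing, alleles and the transgene sequences were not analysed here, and neither whole brain against the other tissues nor age was compared, since age, Y-linked counts and table differ together.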

Results

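Microglia sorted as CD11b+ CD45lo cells from C57BL/6 mice were profiled by bulk RNA sequencing. The 42 libraries form 11 groups. Libraries are named by condition and animal (SPF1, GF529, and GFA518 for acetate). Whole brain holds wild-type mice kept specific-pathogen-free (SPF, n = 3) or germ-free (GF, n = 5), aged 6 to 12 weeks. Cortex holds wild-type SPF, GF and GF mice given acetate in the drinking water (n = 4 each; for 8 weeks per the labels, which also mention a germ-free group treated for 4 weeks, not placed by library), and hippocampus holds these conditions in wild type (n = 4, 3 and 4) and in 5xFAD mice (n = 4, 3 and 4), all aged 16 weeks. 5xFAD mice carry human transgenes, App among them, with familial Alzheimer mutations under the Thy1 promoter, so counts at the mouse App gene are given only as measured. Total counts ran from 19.33 M to 25.37 M in whole brain, from 15.79 M to 23.86 M in cortex and from 5.74 M to 22.53 M in hippocampus. Only wild-type hippocampus SPF4 (5.86 M) and 5xFAD SPF2142 (5.74 M), called the shallow libraries, lay below 15.06 M.

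Sex-linked genes separate the tissues. The 8 whole-brain libraries had 0 CPM of Y-linked Ddx3y and 95.22 to 191.84 CPM of Xist, the RNA of the inactive X chromosome. All cortex and hippocampus libraries had 63.58 to 148.88 CPM of Ddx3y and at most 3.3 CPM of Xist. Microglial genes were abundant in every group: P2ry12, a purine receptor of resting microglia, averaged 11400 CPM in whole-brain SPF, 6290 CPM in cortex SPF and 6760 CPM in hippocampus SPF wild type. Markers of other cells were low but not absent. Neutrophil genes averaged 4.194 on the log2(CPM + 1) scale in 5xFAD library SPF2153 (0.853 to 0.871 in the other 3), and erythroid genes 2.895 in hippocampus SPF wild-type library 3 (0.093 to 0.287 in the other 3). T and NK cell genes stayed between 0.04 and 0.22 in the group means, neuronal genes between 0.51 and 0.83, and oligodendrocyte genes between 2.86 and 3.32. Hippocampus GF530 and GFA518 had fewer genes detected (17750 and 16607) at 16.47 and 21.75 M counts.

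**Figure D1:**
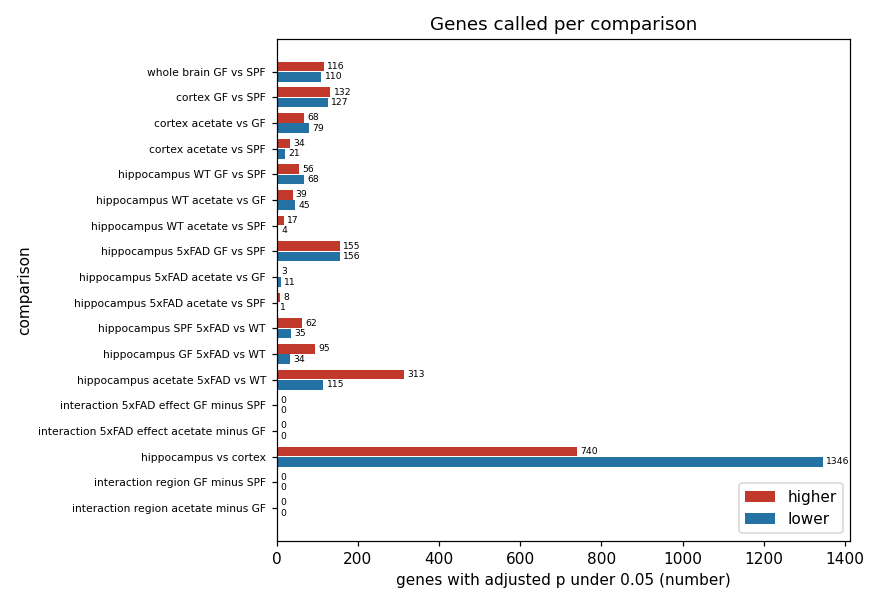
Number of genes with adjusted p under 0.05 (x axis) in each of the 18 comparisons (y axis), higher (red) and lower (blue) in the group named ahead of "vs". Counts run from 0 in each of the 4 interactions to 2086 between hippocampus and cortex.

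Which genes differ in microglia of mice without bacteria was asked in whole brain, GF (n = 5) against SPF (n = 3). Ddit4, an inhibitor of the growth kinase mTORC1, rose 16.8-fold (log2 4.07, SE 0.26, adjusted p = 1.8e-06), from 2.8 (SD 0.701) to 47.2 (SD 12) CPM. Wdfy1, an endosomal protein, rose 13.1-fold from 8.48 (SD 2.08) to 112 (SD 8.63) CPM (adjusted p = 1.8e-08). The clock gene Per1 rose 5.38-fold (adjusted p = 0.00012) and Egr1, an immediate-early transcription factor, 4.51-fold (adjusted p = 0.0015). Apoe, the main lipid carrier of the brain, rose 2.55-fold from 289 (SD 43.1) to 736 (SD 211) CPM (adjusted p = 0.01). Mpeg1, the pore-forming perforin-2 of macrophages, fell from 785 (SD 114) to 340 (SD 84.9) CPM (log2 -1.21, SE 0.16, adjusted p = 0.0014). In all, 116 genes were higher and 110 lower among 11332 tested.

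Other large whole-brain rises were Camk2b (11.4-fold, adjusted p = 0.0069), the beta-adrenergic receptor Adrb1 (3.7-fold, 3.4e-05), the AP-1 family member Jdp2 (3.7-fold, 0.013) and the galectin Lgals3 (3.14-fold, 0.013). Gpr137b-ps fell 8.46-fold, from 43.3 (SD 0.871) to 5.13 (SD 0.455) CPM (2.2e-08), while its parent gene Gpr137b rose by log2 1.11 (3e-05); reads of such near-identical copies can be assigned to either. Adcy8 (log2 -2.00, 0.021), Ero1lb (log2 -1.22, 0.0014) and the deacetylase Hdac9 (log2 -1.08, 0.026) fell. The 4 succinate dehydrogenase genes, which make up respiratory complex II, did not pass: Sdha log2 0.03, Sdhb 0.18, Sdhc 0.18 and Sdhd 0.06 (adjusted p = 0.88, 0.22, 0.43 and 0.77). The acetyl-CoA synthetase Acss2 had log2 2.02 (SE 0.51, 0.058) and mitochondrial Acss1 -0.02 (0.95). Trem2 (-0.06), Clec7a (0.44), Cst7 (-0.10), P2ry12 (-0.13) and Tmem119 (0.09) did not pass either.

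By list, 6 of 32 disease-associated genes were higher, 1 lower and 25 did not pass in whole brain (8 and 1 adjusted over the list alone); Lgals3 and Apoe were among the higher, and the tetraspanin Cd9 was the lower one (log2 -0.46, SE 0.05). The list lay above other genes by camera (adjusted p = 0.0016, median log2 0.17; adjusted p = 0.76 with an estimated correlation). Immediate-early genes (2 higher, 1 lower, 21 not passing of 24; 8 and 2 adjusted over the list alone) had adjusted p = 0.017 by camera, 0.76 with an estimated correlation, and 0.066 without GF library 1. Nr4a1 was higher (log2 2.03, SE 0.44) and Ier5 lower (log2 -0.59). None of 69 ribosomal protein genes passed, and the list lay lower by camera (median log2 -0.20, adjusted p = 0.0016; adjusted p = 0.91 with an estimated correlation). Phagocytosis and lysosome genes had 6 higher and 1 lower of 33 (10 and 3 adjusted over the list alone), among them the Fc receptors Fcgr3 (log2 0.47, SE 0.04) and Fcgr2b (log2 -0.41, SE 0.07) in opposite directions. Inflammatory genes also split: the chemokines Ccl4 (log2 1.43) and Ccl3 (log2 1.35) rose, while Tlr2 (log2 -0.35) and Nfkb1 (log2 -0.46) fell. Of 23 homeostatic genes Crybb1 rose (log2 0.66) and P2ry13 (log2 -0.32) and Cx3cr1 (log2 -0.19) fell. Interferon and MHC lists are among those with no camera call. Tests were edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. The number of calls was 83, 118 and 101 without SPF 1, 3 and 4 in turn, and 133 without GF 4.

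The same question was asked in cortex at 16 weeks, GF against SPF (n = 4 each). Zbtb16, a zinc-finger transcription factor, rose from 0.102 (SD 0.165) to 20.4 (SD 14.5) CPM (191-fold, log2 7.58, SE 1.12, adjusted p = 0.0037). Pik3ip1, which restrains PI3 kinase, rose 5.68-fold to 56.3 (SD 31) CPM, and the glucose transporter Slc2a3 rose 5.04-fold, both with adjusted p = 0.00045. Apoe rose 2.36-fold (adjusted p = 0.0086). The mannose receptor Mrc1, a marker of border macrophages, fell 3.06-fold to 9.44 (SD 1.9) CPM (adjusted p = 0.0011), and the microglial genes Olfml3 (log2 -0.84, SE 0.1) and Fcrls (log2 -0.93, SE 0.12) fell. In all, 132 genes were higher and 127 lower among 15113 tested.

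Further cortical rises were Plet1os (16.2-fold, adjusted p = 0.01; an RNA antisense to its neighbour, so strand assignment is uncertain), Hif3a (6.87-fold, 0.02), the inhibitory receptor Cd300lf (6.21-fold, 0.0042), Ston1 (6.01-fold, 9e-04) and the acid-sensing receptor Gpr65 (5.09-fold, 0.0036). Lag3 (2.2-fold, 0.00055), Ncs1 (2.19-fold, 0.00095) and Rell1 fell, as did the histone genes H3c6 (3.1-fold) and H2ac8, whose copies share sequence. Sdha (log2 0.02), Sdhb (-0.01), Sdhc (0.03) and Sdhd (0.08) did not pass, nor did Acss1 (-0.28), Trem2 (-0.32), P2ry12 (-0.22, adjusted p = 0.43), Tmem119 (-0.16) or Clec7a (0.23).

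Homeostatic genes lay lower in GF cortex: 1 higher, 3 lower and 19 not passing of 23 (1 and 7 adjusted over the list alone), median log2 -0.22, camera adjusted p = 2.2e-07 (adjusted p = 0.67 with an estimated correlation). Sparc was the other lower gene (log2 -0.44), and Crybb1 the higher (log2 0.53). Phagocytosis and lysosome genes had 1 higher and 2 lower of 33 (1 and 8 adjusted over the list alone), with Fcgr3 up (log2 0.53) and Fcgr2b and Hexa down (log2 -0.40 and -0.44). That list had camera adjusted p = 0.0035, 0.88 with an estimated correlation, and 0.058 without GF532. Unfolded protein and heat shock genes (0 and 0 of 21; 0 and 1 adjusted over the list alone) had median log2 -0.15 and camera adjusted p = 0.0065, 0.88 with an estimated correlation, and 0.12 without GF529. Of the lists without a camera call, disease-associated genes had 2 higher (Apoe and Lilrb4a, log2 1.12) and 28 not passing of 30. Immediate-early genes had 2 higher (Nr4a1, log2 1.80, and Klf6, log2 0.43), and inflammatory genes 2 lower (Tlr2, log2 -0.58, and Icam1, log2 -0.45). Respiratory complex II (0 of 4), the TCA cycle (0 of 26) and the acetate list (0 of 14) had medians of log2 0.02 each. Calls numbered 166 and 156 without SPF 1 and 2, and 136, 124 and 162 without GF528, GF529 and GF532; a fit of only these groups gave 153.

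Genes called in whole brain were then looked up in the other tissues, where all mice had Y-linked counts. Of the 116 whole-brain rises, 112 were tested in cortex and 27 were called higher and 0 lower in GF cortex; of the 110 falls, 106 were tested and 0 were called higher and 21 lower. Both gene groups moved in their whole-brain direction by camera with an estimated correlation (adjusted p = 0.042 each). In hippocampus the counts were 9 and 0, and 0 and 4, in wild type, and 15 and 4, and 1 and 12, in 5xFAD; only the falls had a camera call with an estimated correlation (0.042 in both, against 0.064 and 0.072 for the rises). The whole-brain falls lay higher with acetate than in GF by fry, which tests a set on its own (adjusted p = 0.016 in cortex, 0.016 in wild-type hippocampus and 0.038 in 5xFAD hippocampus), with 5, 3 and 0 of their genes called higher. With an estimated correlation camera gave 0.071, 0.064 and 0.084. The whole-brain rises did not pass by fry (0.19, 0.43 and 0.68, medians of log2 -0.043, 0.044 and 0.046), with 14, 5 and 2 called lower and 2, 0 and 0 higher.

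What acetate changes in germ-free mice was asked in cortex, acetate against GF (n = 4 each). Zbtb16 fell to 0.426 (SD 0.758) CPM, 45.4-fold below GF (log2 -5.51, SE 0.93, adjusted p = 0.014). Fkbp5, a co-chaperone of steroid receptors, fell from 802 (SD 168) to 154 (SD 79.7) CPM (5.21-fold, adjusted p = 0.034), and Pik3ip1 fell 4.32-fold (adjusted p = 0.0017). Olfml3 rose (log2 0.73, SE 0.1, adjusted p = 0.0017), with the fructose transporter Slc2a5 (log2 0.63), Sparc (0.57) and Fcrls (0.61). P2ry12 averaged 7300 (SD 744) CPM against 5400 (SD 743) and did not pass (log2 0.43, adjusted p = 0.085). In all, 68 genes were higher and 79 lower.

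Among the rises with acetate in cortex were the receptor Acvrl1 (2.18-fold, adjusted p = 0.0013), Fam89a (log2 1.14), the myosin Myo1e (log2 1.05, 0.0026), Gadd45g (log2 1.01, 0.028) and Ncs1 (1.77-fold, 0.014). The falls included Plet1os (16.3-fold, 0.017), Hif3a (15.8-fold, 0.0068), Ston1 (6.67-fold, 0.0013), Cd300lf (5.22-fold, 0.014) and Jdp2 (4.16-fold, 0.0084). Sdha (log2 0.02), Sdhb (-0.06), Sdhc (0.01) and Sdhd (-0.02) did not pass, nor did Apoe (-0.57, adjusted p = 0.3), Acss1 (0.31), Acss2 (-0.07), Clec7a (0.83, 0.11) or Tmem119 (0.32).

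Homeostatic genes had 5 higher, 0 lower and 18 not passing of 23 with acetate in cortex (15 and 0 adjusted over the list alone). Their median was log2 0.31, with camera adjusted p = 1.8e-12, 0.17 with an estimated correlation, and 0.024 by fry. Unfolded protein genes had 2 higher of 21 (Sdf2l1, log2 0.59, and Calr, log2 0.47; 8 and 0 adjusted over the list alone; camera 5.1e-07, 0.49 with an estimated correlation). Of 22 glycolysis genes, Hk3 rose (log2 0.74) and Slc2a3 fell (log2 -1.51, SE 0.26), with camera Up at 0.0042 (0.49 with an estimated correlation). Ribosomal proteins had 0 calls of 79 and median log2 -0.20 (6.3e-07, 0.87 with an estimated correlation). Lists that lost their camera call without a single library were phagocytosis (1 higher of 33, Itgam, log2 0.67; 0.0087, 0.11 without GF532 and 0.056 without GFA518), MHC class I (0.012, 0.066, 0.064 and 0.052 without GF530, GF532 and GFA523) and MHC class II (0.012, 0.064 and 0.073 without GF532 and GFA524). To these belong mitochondrial DNA-encoded genes (0.028, 0.32, 0.064, 0.45 and 0.052 without GF528, GF532, GFA518 and GFA523) and complex I (0.032, 0.21, 0.13 and 0.45 without GF528, GF529 and GFA518). With an estimated correlation these 5 lists had adjusted p = 0.67, 0.49, 0.49, 0.83 and 0.89. Complex II had 0 calls of 4 (median log2 -0.01), the TCA cycle 0 of 26 (0.01) and the acetate list 0 of 14 (0.08). Immediate-early Klf4 (log2 -2.75) and Nr4a1 (log2 -1.59) fell, and the astrocyte gene Slc1a3 fell (log2 -0.58). Calls numbered 23, 44 and 77 without GF528, GF529 and GF532, and 35, 29 and 32 without GFA523, GFA524 and GFA525; a fit of only these groups gave 316.

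The genes that acetate moved were then set against those that GF moved. In cortex, 40 genes were higher in GF and lower with acetate and 35 lower in GF and higher with acetate, among them Zbtb16, Pik3ip1, Olfml3 and Fcrls. In hippocampus the counts were 17 and 17 in wild type and 9 and 3 in 5xFAD. The 2 contrasts share the GF libraries, which alone makes their folds run against each other and favours such counts. Their covariance across genes was -0.1288 in cortex, where simulations without any change gave -0.0698 on average, -0.3091 in wild-type hippocampus (simulated -0.1918) and -0.2459 in 5xFAD hippocampus (simulated -0.2068). With the 4 cortex GF libraries parted so that neither contrast shares one, r across genes was -0.209 to -0.157 over 6 splits. Genes are not independent replicates.

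**Figure D2:**
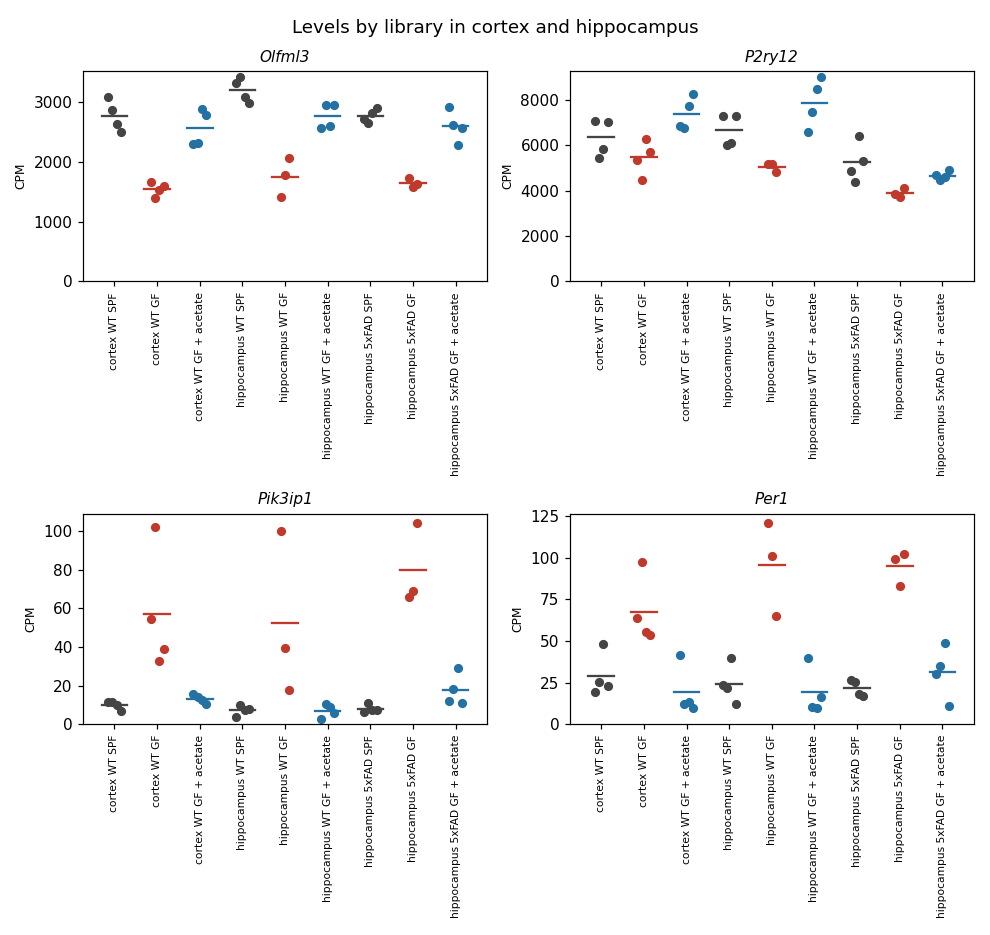
CPM (y axes) of Olfml3, P2ry12, Pik3ip1 and Per1 in each cortex and hippocampus library, by group (x axes); points are libraries and lines group means. Pik3ip1 averages 9.91, 56.3 and 13 CPM in cortex SPF, GF and GF with acetate, and P2ry12 6760, 5100 and 7950 CPM in the same conditions of wild-type hippocampus.

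How far acetate-treated germ-free mice still differ from SPF was asked in cortex (n = 4 each). Glrp1 stayed 3.71-fold above SPF (59, SD 15.5, against 15.9, SD 4.06 CPM; adjusted p = 6.2e-05) and the lysosomal receptor Gpr137b 2.84-fold (160, SD 27, against 56.2, SD 4.52 CPM; 5.8e-05). Mrc1 was 2.97-fold lower (9.7, SD 2.49, against 28.8, SD 6.03 CPM; 0.0022) and the replication helicase Mcm6 5.13-fold lower (0.011). Olfml3 (log2 -0.11, adjusted p = 0.905), Apoe (log2 0.67, 0.43) and P2ry12 (log2 0.21, 0.78) did not pass. In all, 34 genes were higher and 21 lower.

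Other genes higher with acetate than in SPF cortex were Kcp (3.35-fold), Hmgn3 (log2 1.63), Tmem181b-ps (2.89-fold, a pseudogene with a near-identical parent), Rgs11 (log2 1.51), Dynlt1b (log2 1.45) and the calpain Capn2 (log2 1.39). Lower were Mlph (3.61-fold, adjusted p = 0.02), D2hgdh (2.59-fold, 0.0017), Ero1b (2.59-fold, 0.016), the interleukin-33 receptor Il1rl1 (log2 -1.24, 0.032) and the cholesterol synthesis gene Dhcr7 (2.07-fold, 0.023). The disease-associated gene Serpine2 was higher (log2 0.72, SE 0.11, 0.0032), while Clec7a did not pass (log2 1.06, 0.076). Nnt, the mitochondrial transhydrogenase (log2 0.86, 0.0022), and Wdfy1 (log2 1.35, 0.0014) were higher than in SPF; both were also higher in GF (log2 0.71 and 0.91) and neither passed between acetate and GF (log2 0.14 and 0.44). Nnt, Wdfy1 and Gpr137b were set side by side over the tissues after their values were seen.

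The 4 border macrophage genes tested had 0 higher and 1 lower, Mrc1 (0 and 2 adjusted over the list alone; median log2 -0.41; camera adjusted p = 8e-05, 0.31 with an estimated correlation). MHC class II (0 and 0 of 9; 3 and 0 adjusted over the list alone; median log2 0.32) had camera adjusted p = 0.00025 and 0.42 with an estimated correlation; H2-Ab1 led at log2 0.95 (SE 0.22, 0.092). Mitochondrial DNA-encoded genes (0 and 0 of 8, median log2 -0.28) had 0.00029, 0.93 with an estimated correlation and 0.13 without GFA518. Ribosomal proteins (0 and 0 of 79, median log2 -0.18) had 1.6e-05, 0.98 with an estimated correlation, and 0.13 and 0.24 without SPF 3 and GFA518. Disease-associated genes had 1 higher (4 and 1 adjusted over the list alone) and no camera call (0.35). Calls numbered 30 and 35 without SPF 2 and 3, 25, 33 and 35 without GFA523, GFA524 and GFA525, and 85 with no filter on low counts.

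**Figure D3:**
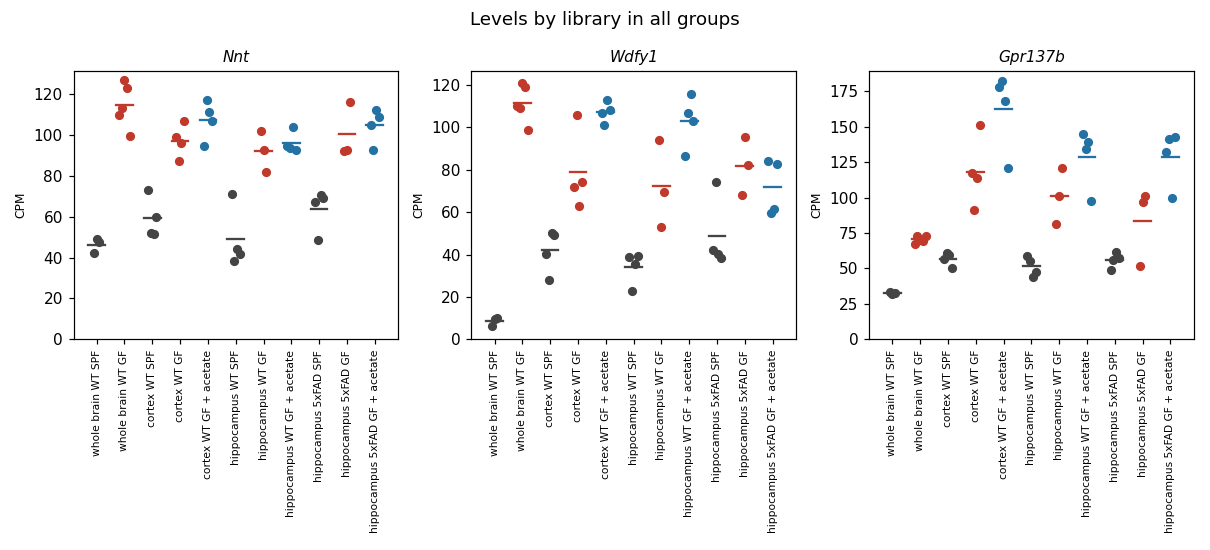
CPM (y axes) of Nnt, Wdfy1 and Gpr137b in each library, by group (x axes); points are libraries and lines group means. Wdfy1 averages 8.48 and 112 CPM in whole-brain SPF and GF, and Gpr137b 56.2 and 160 CPM in cortex SPF and GF with acetate.

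In wild-type hippocampus, GF (n = 3) was set against SPF (n = 4) to ask whether another region responds. Zbtb16 rose from 0.0687 (SD 0.137) to 31.8 (SD 23.6) CPM (374-fold, log2 8.55, SE 1.43, adjusted p = 0.0082). Pik3ip1 rose 7.17-fold (adjusted p = 0.0048), the receptor Notch4 4.64-fold from 19.9 (SD 10.2) to 94.4 (SD 34.4) CPM (0.0089), and Per1 3.88-fold to 96.6 (SD 28.3) CPM (0.032). Olfml3 fell (log2 -0.87, SE 0.11, adjusted p = 0.00022), and Fcrls fell 2.14-fold from 3300 (SD 242) to 1540 (SD 211) CPM (0.019). Apoe (log2 0.70, 0.61) and P2ry12 (log2 -0.40, SE 0.12, 0.1) did not pass. In all, 56 genes were higher and 68 lower among 17063 tested.

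Other hippocampal rises in GF were Plet1os (121-fold, antisense), Sgip1 (6.07-fold, adjusted p = 0.0042), Afdn (4.09-fold) and Klf2 (3.44-fold, 0.025). The falls included the cytokine subunit Ebi3 (2.42-fold, 0.0042), Gorab (log2 -1.25), Prkar1b (log2 -1.25, 0.031), Lst1 (2.12-fold) and Lag3 (2.1-fold). Sdha (log2 0.08), Sdhb (-0.12), Sdhc (-0.19), Sdhd (-0.04), Trem2 (-0.37), Tmem119 (-0.34) and Clec7a (-0.61) did not pass. Homeostatic genes had 0 higher, 4 lower and 19 not passing of 23 (0 and 13 adjusted over the list alone), median log2 -0.34, camera adjusted p = 1.5e-08 (adjusted p = 0.35 with an estimated correlation); Sparc (log2 -0.57) was among the others called. Unfolded protein genes had 1 lower of 22, Canx (log2 -0.45), and 8 adjusted over the list alone (median log2 -0.33, 1.6e-06, 0.35 with an estimated correlation). Phagocytosis genes had 2 lower of 34, among them Hexa (log2 -0.64), and 7 adjusted over the list alone (1.2e-06, 0.64 with an estimated correlation).

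4 lists lost their camera call in hippocampus without GF529. Disease-associated genes had 2 lower of 35, Cd9 (log2 -0.90, SE 0.18) and Timp2 (-0.46), median log2 -0.32 and adjusted p = 0.0055, against -0.21 and 0.17 without GF529. Proliferation (median log2 -0.38, 0.0072), MHC class I (-0.25, 0.0079) and glycolysis (-0.21, 0.018) had 0 calls and 0.076, 0.23 and 0.18 without it. Estimating the correlation, the 4 had adjusted p = 0.78, 0.72, 0.72 and 0.7. The LXR target Mylip fell (log2 -0.68). Complex II (median log2 -0.08), the TCA cycle (-0.02) and the acetate list (-0.11) had 0 calls. Calls numbered 75, 55 and 33 without SPF 1, 2 and 4, and 25 and 58 without GF529 and GF530. They numbered 78 with the shallow libraries left out, 151 without SPF2152, GFA518 and GF530, and 34 in a fit of only these groups.

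Acetate was set against GF in wild-type hippocampus (n = 4 and 3). P2ry12 rose from 5100 (SD 199) to 7950 (SD 1100) CPM (1.56-fold, log2 0.64, SE 0.12, adjusted p = 0.013). Olfml3 (log2 0.66, SE 0.11, 0.0059), P2ry13 (log2 0.66) and Gpr34 (log2 0.55) rose as well. Pik3ip1 fell 7.61-fold from 52.7 (SD 42.8) to 6.94 (SD 3.41) CPM (0.0059), and Per1 4.97-fold to 19.4 (SD 14.3) CPM (0.018). In all, 39 genes were higher and 45 lower.

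Hacd4 (2.1-fold, adjusted p = 0.0078), Lst1 (2.09-fold, 0.029), Tbc1d1 (log2 1.07), Kcnma1 (log2 1.04) and Evi2a (log2 0.90) were higher with acetate in hippocampus. Sgip1 (4.94-fold, 0.012), the phosphatase Phlpp2 (2.96-fold, 0.0038), Adrb1 (2.72-fold, 0.022), Klf13 (2.65-fold, 0.0059) and Ccnd3 (log2 -1.34) were lower. Tmem119 (log2 0.31), Apoe (0.05), Sdha (0.05), Sdhb (0.19), Sdhc (-0.11) and Sdhd (-0.16) did not pass.

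Homeostatic genes had 6 higher, 1 lower (Rhob) and 16 not passing of 23 with acetate (14 and 2 adjusted over the list alone), median log2 0.31, camera adjusted p = 9e-10, 0.36 with an estimated correlation, and 0.031 by fry. Unfolded protein genes had 1 higher, Pdia3 (log2 0.43), of 22 and 8 adjusted over the list alone (median log2 0.33, 0.00031, 0.39 with an estimated correlation). Camera calls that ended without a single library were those of clock genes (1 lower, Per1; median log2 -0.31, adjusted p = 0.031, 0.28, 0.073 and 0.056 without GF529, GFA523 and GFA525), complex I (0 of 36; 0.14, 0.031, 0.33, 0.077, 0.18 and 0.19 without GF529, GF530, GFA523 and GFA525) and phagocytosis (0 of 34; 0.09, 0.031, 0.28, 0.062, 0.073 and 0.091 without the same 4). These 3 had, with an estimated correlation, adjusted p = 0.39, 0.88 and 0.88. Fasn of the acetate list fell (log2 -1.3), as did Nfkbia (log2 -0.91). Calls numbered 35 without GF529 and 130, 51, 30 and 29 without GFA518, GFA523, GFA524 and GFA525. They numbered 127 without SPF2152, GFA518 and GF530 and 0 in an edgeR fit of only these groups, where DESeq2 on the full set gave 376 and 2003 genes had an unadjusted p under 0.05 in the fit reported.

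Acetate was set against SPF in wild-type hippocampus (n = 4 each). Glrp1 stayed 4.07-fold higher (74, SD 12, against 18.3, SD 4.54 CPM; adjusted p = 0.00015), Wdfy1 3.03-fold (0.00085) and Gpr137b 2.49-fold (0.00085). Csmd3, a large adhesion protein, was 2.3-fold higher at 540 (SD 62) CPM (0.00019). Mlph was 3.2-fold lower (0.022), Lag3 2.22-fold (0.015), the sulfide oxidase Sqor 1.75-fold (0.00086) and Sh2b1 1.65-fold (0.023). In all, 17 genes were higher and these 4 lower.

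Tmem181b-ps (3.7-fold), Dynlt1b (3.51-fold), Emp3 (2.6-fold, adjusted p = 0.0047), Kcnma1 (2.06-fold) and Serpine2 (log2 0.71, 0.022) were also higher than in SPF hippocampus, and Nnt was higher (log2 0.97, 0.0047). Sdha (log2 0.13), Sdhb (0.07), Sdhc (-0.31), Sdhd (-0.19), Acss2 (-1.10), Apoe (0.75, 0.72), P2ry12 (0.23, 0.58), Tmem119 (-0.02) and Trem2 (-0.16) did not pass. Of the 35 disease-associated genes Serpine2 alone was called (median log2 -0.14, no camera call). 5 lists without a called gene had a camera call: phagocytosis (median log2 -0.12, adjusted p = 0.026, 0.14 without GFA524), proliferation (-0.27, 0.026, 0.051 to 0.064 without any single one of SPF 2, 3, 4 and GFA523, and a median of 0.10 at 0.58 without GFA518), border macrophages (-0.39, 0.026, 0.22 without SPF 3), monocytes (2.95, 0.026, 0.074 without SPF 1 and 0.15 without GFA518) and endothelial cells (-1.10, 0.044, and 0.12, 0.22, 0.23, 0.11 and 0.05 without SPF 1, SPF 4, GFA518, GFA523 and GFA524). With an estimated correlation they had adjusted p = 0.85, 0.85, 0.39, 0.28 and 0.4. Calls numbered 12 and 13 without SPF 1 and 3, 17 without the shallow libraries, 23 without SPF2152, GFA518 and GF530, and 11 in a fit of only these groups.

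Region itself was tested within 11 wild-type animals, hippocampus against cortex. The transmembrane enzyme Ndst1 was 2.23-fold lower in hippocampus (log2 -1.16, SE 0.13, adjusted p = 0.00012) and Toll-like receptor Tlr12 2.17-fold lower (0.00029). Csf1r, the receptor microglia need to survive, was lower (log2 -0.39, SE 0.04, 6.3e-05), with Tmem119 (1.23-fold, 0.0014) and Sdha (log2 -0.28, SE 0.05, 0.0019). Egr1 was 2.1-fold higher (0.019), Klf4 2.07-fold (0.015) and mt-Rnr2, a mitochondrial ribosomal RNA, 1.85-fold (0.00012). In all, 740 genes were higher and 1346 lower among 16706 tested, 1242 without GF530, and 1356 without animals GFA518 and GF530.

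Mrc1 (2.6-fold, adjusted p = 0.034), Gng7 (2.69-fold, 0.018), Slc39a4 (log2 -1.73) and Wdr19 (log2 -1.26) were also lower in hippocampus, and the cell-cycle inhibitor Cdkn1a higher (log2 0.88, 0.0015). Ribosomal proteins had 41 higher and 0 lower (67 and 0 adjusted over the list alone), median log2 0.34 (camera adjusted p = 6e-28), and complex I 7 higher, among them Ndufv2 (log2 0.41), and 1 lower, Ndufv1 (log2 -0.35), of 36 (11 and 1 adjusted over the list alone; 1.1e-06). Complex IV had 4 higher and 0 lower (11 and 0 adjusted over the list alone; Cox4i1, log2 0.38; 1.1e-06), immediate-early genes 7 higher (12 adjusted over the list alone; 0.00017) and mitochondrial DNA-encoded genes 4 higher (mt-Nd2, log2 0.41; 0.00042). Each of these 5 had adjusted p = 0.49 with an estimated correlation. So had interferon genes (0.017, 0.051 without SPF 2 and 0.1 without GF529), complex V (0.029, 0.062, 0.11 and 0.055 without SPF 1, GF532 and GFA518) and glycolysis (4 lower; 0.036; 0.062, 0.051, 0.18, 0.06 and 0.059 without SPF 1, SPF 3, GF529, GFA518 and GFA524).

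Lists without a camera call between the regions still held many called genes. Homeostatic genes had 5 higher and 7 lower (Cst3, log2 0.37, and Adgrg1, log2 -0.34), disease-associated genes 7 higher and 3 lower (Ccl6, log2 0.62, and Ctsb, log2 -0.38) and phagocytosis genes 3 higher and 10 lower (Grn, log2 -0.34). The TCA cycle had 1 higher and 5 lower (Ogdh, log2 -0.41, and Cs, log2 -0.25), histone acetyltransferases and deacetylases 1 higher and 5 lower (Crebbp, log2 0.30, and Kat2a, log2 -0.53) and the acetate list 2 lower (Acly, log2 -0.48, SE 0.06, and Crat, log2 -0.21). Clock genes Cry1 (log2 -0.69) and Cry2 (-0.55), the oligodendrocyte genes Trf (-0.26) and Cnp (-0.27) and the endothelial genes Kdr (-0.97) and Pecam1 (-0.48) were lower.

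Whether GF or acetate acts differently by region was tested as an interaction. 0 genes passed for GF (edgeR; 900 at unadjusted p under 0.05; 13 by DESeq2) and 0 for acetate (732; 2 by DESeq2), so no gene was shown to differ; Apoe had log2 -0.37 and 0.46, and P2ry12 -0.20 and 0.20. The smallest p-values belonged to the muscle gene Actc1 (log2 -9.27 for GF, adjusted p = 0.49), Tiparp (-1.30, 0.64) and Lpin1 (-0.97 for acetate, 0.99). Without GF529 or without GF532, 1 gene passed in each, and with no filter on low counts 22 and 17. By camera the disease-associated list differed for GF (median log2 -0.24, adjusted p = 0.0018, 0.33 without GF529), as did phagocytosis (-0.14, 0.049) and unfolded protein genes (-0.16, 0.049). Phagocytosis had 0.11, 0.078, 0.18, 0.74 and 0.1 without SPF 2, 3, 4, GF529 and GF530, and unfolded protein genes 0.059, 0.12, 0.12 and 0.11 without SPF 3, 4, GF529 and GF530. Complex I (0.18, 0.00069, 0.27 without GF529 and 0.073 without GFA518) and complex IV (0.22, 0.021; 0.27, 0.13, 0.32 and 0.29 without GF529, GF530, GFA518 and GFA525) differed for acetate. With an estimated correlation these had adjusted p = 0.81 for GF and 0.84 for acetate.

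In 5xFAD hippocampus, GF (n = 3) was set against SPF (n = 4). Zbtb16 rose 40.1-fold from 4.41 (SD 4.8) to 151 (SD 50.1) CPM (log2 5.32, SE 0.99, adjusted p = 0.0069), Pik3ip1 10.1-fold to 80.3 (SD 21.3) CPM (0.00063), Notch4 8.51-fold to 168 (SD 39.5) CPM (0.00022) and Ddit4 20.9-fold (0.04). Chaperones fell: Hsp90ab1 2.62-fold from 951 (SD 494) to 363 (SD 32.7) CPM (0.0093) and Pdia6 (log2 -0.74, SE 0.12, 0.0019). P2ry12 fell 1.36-fold from 5320 (SD 877) to 3910 (SD 208) CPM (0.046), and Olfml3 fell (log2 -0.76, SE 0.11, 0.00043). In all, 155 genes were higher and 156 lower.

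Other rises were Ston1 (13.7-fold, adjusted p = 0.003) and Klf4 (8.66-fold, 0.0089). Falls included the chemokine Ccl12 (4.41-fold from 184, SD 138, to 41.6, SD 8.05 CPM, 0.011), the receptor Ccr1 (3.65-fold, 0.035), Cdkn1a (3.26-fold, 0.042), the NF-kB subunit Relb (2.98-fold, 0.0071) and the heat shock gene Hspa1b (log2 -8.20, SE 1.91, 0.034; it shares most of its sequence with Hspa1a). Unfolded protein genes had 0 higher, 7 lower and 15 not passing of 22 (1 and 14 adjusted over the list alone), among them Manf (log2 -0.84), Calr (-0.56) and Pdia3 (-0.50); median log2 -0.51, camera adjusted p = 1.2e-11, 0.096 with an estimated correlation, and 0.01 by fry. Homeostatic genes had 1 higher (Rhob, log2 0.57) and 7 lower of 23 (1 and 10 adjusted over the list alone; Bin1, log2 -0.61, and P2ry13, log2 -0.69; 0.00012, 0.55 with an estimated correlation). Immediate-early genes had 6 higher and 1 lower of 26 (11 and 5 adjusted over the list alone; Dusp1, log2 2.03, Ier2, 1.57, and Fos, 1.82; 0.00066, 0.55 with an estimated correlation); their median was log2 0.40 and their mean -0.03.

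The other camera calls in 5xFAD GF against SPF were lost when certain libraries were left out in turn. Inflammatory genes (1 higher, Nfkbia, log2 1; 2 lower, Icam1, log2 -0.94, and Relb; adjusted p = 0.017) had 0.071 without SPF2142 and 0.058 without GF531. Border macrophages (median log2 -1.52, 0.017, 0.055 without GF531), MHC class II (-0.96, 0.019, 0.11 without SPF2142 and 0.066 without GF531), glycolysis (-0.30, 0.021, 0.32, 0.11 and 0.098 without SPF2142, GF527 and GF531) and phagocytosis (-0.10, 0.043; 0.2, 0.68, 0.13 and 0.54 without SPF2140, SPF2142, GF527 and GF531) had at most 1 called gene each. With an estimated correlation these 5 had adjusted p = 0.31, 0.29, 0.55, 0.55 and 0.98. Without 5xFAD library SPF2152, disease-associated genes gained a call (-0.23, 0.0032), and interferon (-0.67, 3e-04), MHC class I (-0.39, 3e-04) and ribosomal genes (-0.15, 0.0017) gained one, none with an estimated correlation (0.69, 0.69, 0.34 and 0.82). Calls numbered 178 without SPF2140 and 202, 117 and 107 without GF526, GF527 and GF531; they numbered 319 without SPF2152, 477 without SPF2152, GFA518 and GF530, and 245 without the shallow libraries.

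Acetate was also set against GF in 5xFAD hippocampus (n = 4 and 3). Among the 3 genes higher were Olfml3 (1.57-fold, 2610, SD 276, against 1660, SD 76.4 CPM; adjusted p = 0.0089) and Marcks (1.41-fold, 0.043). Of the 11 lower, the glycerol-phosphate dehydrogenase Gpd1 fell 3.07-fold from 62.9 (SD 2.16) to 20.5 (SD 3.17) CPM (0.0089) and Ppp1r21 2.44-fold (0.00053). Rnf169 (log2 -1.26), Klf13 (2.22-fold), Lifr (2.21-fold), Chka (log2 -1.04), Rcan1 (-1.04) and Rbm26 (-0.90) fell too. Per1 did not pass (log2 -1.60, SE 0.43, 0.19).

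15 lists had a camera call for acetate against GF in 5xFAD, and none held with an estimated correlation. The 5 with the lowest adjusted p were ribosomal proteins (median log2 0.24, adjusted p = 2.3e-10, 0.38 with an estimated correlation), phagocytosis (0.22, 2.8e-09; 0.19), MHC class I (0.37, 9.1e-08; 0.19), homeostatic (0.19, 1.9e-07; 0.19) and disease-associated genes (0.32, 1.9e-07; 0.33). Olfml3 was the 1 member called in any of the 15; adjusted over the list alone, 8 homeostatic, 7 MHC class I, 6 unfolded protein and 6 glycolysis genes were higher. MHC class II (1.20, 7e-06), unfolded protein (0.20, 1.6e-05), glycolysis (0.26, 3e-04) and clock genes (-0.34, 0.00094) each had 0.19 with an estimated correlation. Complex I (0.15, 0.00013; 0.36), V (0.22, 0.00016; 0.33) and IV (0.24, 0.001; 0.38) lay higher. Interferon genes (0.66, 0.00012, 0.38 with an estimated correlation) had 0.087 without GFA521, inflammatory genes (0.35, 0.016; 0.19) 0.065 without GF531 and 0.055 without GFA522, and immediate-early genes (-0.13, 0.02; 0.43) 0.16, 0.091 and 0.061 without GF526, GFA521 and GFA522. The 14 calls became 8, 2 and 2 without GF526, GF527 and GF531, and 2, 4, 38 and 3 without GFA519, GFA520, GFA521 and GFA522. They became 61 without SPF2152, GFA518 and GF530, 23 without the shallow libraries, 30 with no filter, 46 at a mean of at least 5 CPM and 121 in a fit of only these groups.

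Between acetate and SPF in 5xFAD hippocampus (n = 4 each), 8 genes were higher and 1 lower. Glrp1 was 2.63-fold higher (46.8, SD 16.1, against 17.8, SD 1.62 CPM; adjusted p = 0.017), Gpr137b 2.3-fold (130, SD 20.7, against 56.5, SD 5.56 CPM; 0.011), Tmem181b-ps 2.39-fold (0.032), Arl4c 2.02-fold (0.016) and Serpine2 1.62-fold (0.044). Stk25 was 2.04-fold lower (0.017). 9 lists had a camera call and none held with an estimated correlation. Disease-associated genes (1 higher; 2 adjusted over the list alone; median log2 0.30, 8.5e-10) had 0.074 without SPF2152, and 0.56 with an estimated correlation. Ribosomal proteins (0.21, 8.5e-10, 0.58 with an estimated correlation) also had 0.074 without SPF2152, and unfolded protein genes (-0.22, 3.6e-05) had 0.56 with an estimated correlation. Phagocytosis (0.13, 0.0022), MHC class I (0.22, 0.0029), mitochondrial DNA-encoded (0.22, 0.0056) and clock genes (-0.23, 0.013) had 0.53, 0.53, 0.17 and 0.064 without SPF2152, and 0.56 with an estimated correlation. Mitochondrial genes also had 0.07 and 0.079 without SPF2153 and GFA522, and clock genes 0.16 without GFA522. Interferon genes (0.24, 0.021, 0.64 with an estimated correlation) had a median of -0.06 without SPF2152 and of -0.12 without GFA521, and 0.092 and 0.055 without SPF2153 and GFA522. Complex IV (0.14, 0.046; 0.63) had 0.68, 0.45, 0.15 and 0.3 without SPF2152, SPF2153, GFA519 and GFA520. Calls numbered 1 without SPF2140 and 1 without GFA519, 9 without SPF2152, 38 without SPF2152, GFA518 and GF530, 2 without the shallow libraries, 5 at a mean of at least 5 CPM and 2 in a fit of only these groups.

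The response to the 5xFAD genotype was asked within each condition, first in SPF hippocampus (n = 4 each). Cst7, an inhibitor of lysosomal proteases that marks disease-associated microglia, rose from 16 (SD 6.04) to 343 (SD 227) CPM (21.9-fold, log2 4.45, SE 0.66, adjusted p = 0.0038). Apoe rose 10.5-fold to 3540 (SD 2440) CPM (0.0038), the growth factor Igf1 25.4-fold (0.0051) and Baiap2l2 76.3-fold (0.0046). App counts were 1.4-fold higher (207, SD 13.7, against 148, SD 10.6 CPM; 0.047). Fos fell 3.49-fold from 174 (SD 73.8) to 49.8 (SD 18.7) CPM (0.017) and Fcrls 1.97-fold (0.017). In all, 62 genes were higher and 35 lower.

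5xFAD library SPF2152 lay far below the other 3 for the disease-associated list, and above wild type. On a scale of 17 list genes from SPF wild type (0) to the other 3 SPF 5xFAD libraries (1) it stood at 0.2; the 4 wild-type libraries lay between -0.02 and 0.02 and the other 3 between 0.94 and 1.06. Without it, 200 genes were higher and 127 lower. Calls numbered 29, 26 and 58 without wild-type SPF 2, 3 and 4, and 34, 29 and 44 without SPF2140, SPF2142 and SPF2153. They numbered 457 without SPF2152, GFA518 and GF530, 21 without the shallow libraries and 10 in a fit of only these groups.

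**Figure D4:**
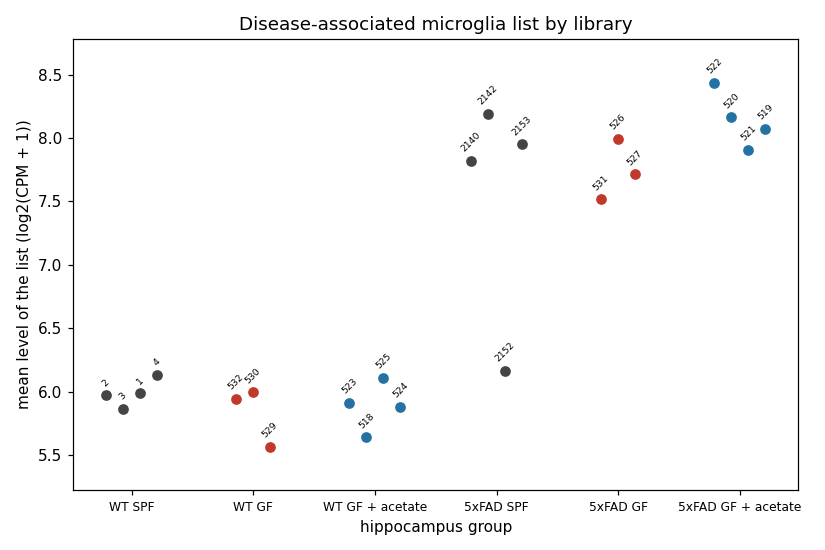
Mean level of the disease-associated microglia list (y axis, log2(CPM + 1)) in each hippocampus library (points, numbered by animal), by group (x axis). On the scale of 17 list genes, SPF2152 lies at 0.2 and the other 3 SPF 5xFAD libraries at 0.94 to 1.06.

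Other SPF rises were Etl4 (171-fold, adjusted p = 0.0016), the oxysterol enzyme Ch25h (51.5-fold, 0.045), Wfdc17 (43-fold, 0.0062), the oxidase subunit Cybb (25.7-fold, 0.012) and Bhlhe40 (19.7-fold, 0.035). Fosb (6.37-fold, 0.012), Dusp1 (3.03-fold, 0.016), Junb (2.06-fold) and Sgk1 (log2 -0.86) fell. Disease-associated genes had 16 higher, 0 lower and 19 not passing of 35 (34 and 0 adjusted over the list alone; Lilrb4a, log2 2.75, and Ank, 1.89), median log2 1.87, camera adjusted p = 4.8e-53 and 0.027 with an estimated correlation. It is the 1 list of the 11 with a camera call in SPF that held. Interferon genes had 3 higher of 30 (23 adjusted over the list alone; Ifi27l2a, log2 2.89, Oasl2, 3.04, and Ifit3, 2.48; median 2.05; 8.5e-25, 0.084 with an estimated correlation). Phagocytosis genes had 5 higher of 34 (14 and 1 adjusted over the list alone; Axl, log2 3.28, and Ctsb, 0.74; 8.9e-12, 0.1 with an estimated correlation), and homeostatic genes 3 lower of 23 (8 adjusted over the list alone; Rhob, log2 -0.66, and Ltc4s, -0.57; 1.6e-11, 0.084 with an estimated correlation). Immediate-early genes had 5 lower (3 and 11 adjusted over the list alone; median log2 -0.39, 5.5e-05, 0.41 with an estimated correlation). Glycolysis (0 called, 8 adjusted over the list alone; 9.5e-07), MHC class I (H2-D1 higher, log2 1.29; 0.00031), MHC class II (0.00077) and border macrophages (median log2 1.11, 0.014; Cd163 log2 6.05, not passing at 0.12) had 0.084, 0.43, 0.22 and 0.11 with an estimated correlation. Ribosomal proteins (median log2 0.24, 7.5e-09, 0.61 with an estimated correlation) had 0.08 and 0.28 without the shallow libraries. Complex IV (0.19, 0.03; 0.61) had 0.35, 0.09, 0.12 and 0.67 without wild-type 1 and 4 and SPF2140 and SPF2142.

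In GF hippocampus (n = 3 each) Cst7 rose from 8.54 (SD 3.67) to 471 (SD 124) CPM (55.2-fold, log2 5.79, SE 0.81, adjusted p = 0.0014) and Apoe 10.2-fold to 5590 (SD 1590) CPM (0.006). Itgax, an integrin of activated microglia, rose 13.1-fold to 56.2 (SD 5.92) CPM (0.026), Igf1 80.3-fold (0.0014) and the receptor kinase Axl 16.5-fold (0.0023). Baiap2l2 had no counts in the 3 wild-type GF libraries and was at least 166-fold higher (26.8, SD 6.63 CPM; 0.0014), and Mamdc2, also without counts there, at least 81.6-fold (0.019). In all, 95 genes were higher and 34 lower.

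Etl4 (1390-fold, adjusted p = 0.00027) and the lipase Lpl (15.2-fold, 0.019) were also higher in GF 5xFAD, and Batf3 (2.67-fold, 0.014), Fchsd2 (1.89-fold, 0.0014), Hpgd (1.8-fold, 0.0014) and Hivep1 (log2 -1.42) lower. Disease-associated genes had 18 higher, 0 lower and 17 not passing of 35 (29 and 0 adjusted over the list alone; Ank, log2 2.62, and Ctsb, 1.09), median log2 1.58, camera adjusted p = 2.6e-58 and 0.013 with an estimated correlation, again the 1 list that held so. By fry 4 lists passed, the others being phagocytosis (0.007), cholesterol synthesis (0.012) and glycolysis (0.032). Phagocytosis genes had 10 higher of 34 (16 adjusted over the list alone; Hexa, log2 0.93, and Ctsd, 0.89; 8.3e-17, 0.08 with an estimated correlation) and interferon genes 3 higher of 30 (16 adjusted over the list alone; Ifitm3, log2 3.39, and Oas1a, 3.19; 2.8e-18, 0.17 with an estimated correlation). Homeostatic genes had 0 called (0 and 4 adjusted over the list alone; median log2 -0.15, 8e-05, 0.32 with an estimated correlation). MHC class I (H2-D1, log2 1.42), mitochondrial DNA-encoded (mt-Nd5, log2 0.66) and proliferation genes (Mki67, log2 5.70) had 1 higher each and 6.4e-05, 6.4e-05 and 1e-05, each 0.32 with an estimated correlation. Glycolysis (median log2 0.36, 6.4e-05, 0.18 with an estimated correlation) had 0 called. Cholesterol synthesis (0.36, 0.0038) and ribosomal proteins (0.24, 6.4e-05) had 0.15 and 0.75 with an estimated correlation, and 0.098 and 0.087 without GF530. Calls numbered 31 and 65 without GF530 and GF532, and 46, 52 and 77 without GF526, GF527 and GF531. They numbered 199 without SPF2152, 145 without SPF2152, GFA518 and GF530, and 149 without the shallow libraries.

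With acetate (n = 4 each) Cst7 rose from 10.1 (SD 1.62) to 619 (SD 133) CPM (61.2-fold, log2 5.94, SE 0.71, adjusted p = 9.2e-05) and Apoe 10.7-fold from 567 (SD 124) to 6060 (SD 1390) CPM (0.00059). Clec7a rose 8.6-fold (0.034), Itgax 9.1-fold (0.0093), Igf1 306-fold (4.3e-05) and Trem2, the lipid receptor upstream of the disease-associated state, 1.35-fold (0.033). P2ry12 fell 1.69-fold from 7950 (SD 1100) to 4700 (SD 209) CPM (0.00024), and Klf2 4.29-fold (0.0015). In all, 313 genes were higher and 115 lower.

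Further rises with acetate were Baiap2l2 (397-fold, adjusted p = 0.00012), Ch25h (80.8-fold, 0.0093), Etl4 (76.6-fold, 9.2e-05), Ifi207 (49.2-fold), Actr3b (35.6-fold) and Mamdc2, at least 72.8-fold above wild type, which had no counts (0.0032). Fgf11 (3.48-fold), Btbd3 (log2 -1.39) and Tmem204 (-1.10) fell. 6 of the 16 lists with a camera call held with an estimated correlation. They were disease-associated (31 higher and 4 not passing of 35; 34 adjusted over the list alone; median log2 2.61; camera 5.7e-76, 0.0039 with an estimated correlation), phagocytosis (18 higher of 34; 22 and 1 adjusted over the list alone; 8.5e-28, 0.011), interferon (17 of 30; 26 adjusted over the list alone; 2.4e-30, 0.03), MHC class I (8 of 18; 13 adjusted over the list alone; 4.4e-14, 0.03), glycolysis (9 of 22; 13 and 1 adjusted over the list alone; 4.8e-09, 0.03) and the acetate list (3 of 14; 4 adjusted over the list alone; 0.00056, 0.03). Ank (log2 2.85), Gusb (1.04), Oas1a (4.14), H2-D1 (1.65), Pkm (1.01) and Acaca (2.30, SE 0.33, 0.00035) led them in that order; Fasn (1.37) and Slc16a3 (0.87) were the other acetate-list rises.

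Homeostatic genes had 5 lower and 0 higher of 23 in acetate 5xFAD (8 adjusted over the list alone; P2ry12, Gpr34, log2 -0.60, Slc2a5, -0.51, and Cx3cr1, -0.39; 4.7e-09, 0.071 with an estimated correlation). Ribosomal proteins had 15 higher (63 adjusted over the list alone; Rpl3, log2 0.61; 1.5e-32, 0.14 with an estimated correlation), and the chemokines Ccl3 (log2 2.14) and Ccl4 (1.57) rose. Markers of other cells were higher beside these genes. Border macrophage genes (Pf4, log2 5.59; median 3.32; 0.0016, 0.071 with an estimated correlation) averaged 1.97 on the log2(CPM + 1) scale against 1.13 in wild type, and endothelial genes (Flt1, log2 5.49; 0.0091, 0.12 with an estimated correlation) 1.69 against 1.11, with 0.053 by camera without GFA518. MHC class II (H2-Ab1, log2 2.01; 0.00027), mitochondrial DNA-encoded (mt-Nd5, log2 0.62; 0.00015) and proliferation genes (median log2 1.17; 2.1e-06) had 0.12, 0.22 and 0.15 with an estimated correlation. Complex IV (0.0033, 0.46 with an estimated correlation, 0.078 without GFA524), complex V (0.03; 0.47; 0.081, 0.28, 0.055, 0.13 and 0.076 without GFA518, GFA524, GFA519, GFA520 and GFA522) and cholesterol synthesis (0.038; 0.19, 0.097 and 0.13 without GFA524 and GFA522) lost their call with a library left out. Calls numbered 271, 252 and 263 without GFA524, GFA520 and GFA522; they numbered 483 without SPF2152, 434 without SPF2152, GFA518 and GF530, and 433 without the shallow libraries.

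The genes called for 5xFAD in the 3 conditions were compared. 26 were higher and 5 lower in all 3 conditions, and 85 and 12 with library SPF2152 left out. SPF and GF shared 27 higher and 5 lower (0.35 and 0.07 expected by chance), SPF and acetate 44 and 12 (1.14 and 0.24 expected), and GF and acetate 69 and 15 (1.74 and 0.23 expected); Apoe, Cst7, Axl, Lpl, Igf1, Ank, Lyz2 and Baiap2l2 were higher in each. Across genes the folds had r = 0.219, 0.241 and 0.248 (Spearman 0.172, 0.196 and 0.245), with genes not independent replicates.

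Whether the 5xFAD response differs by condition was tested as an interaction. GF minus SPF gave 0 genes (edgeR; 942 at unadjusted p under 0.05; 15 by DESeq2) and acetate minus GF 0 genes (905; 7 by DESeq2), so no gene was shown to differ between conditions. Gpd1 (log2 2.02, SE 0.37), Tmem183a (1.19, SE 0.23) and Nav3 (-0.85, SE 0.17) came closest for GF minus SPF (adjusted p = 0.25 each), and Chtop (-1.15, SE 0.2, 0.13) for acetate minus GF. Cst7 had log2 1.33 (SE 0.92) and 0.15 (SE 0.91), Apoe -0.04 and 0.07 (SE 0.69 each) and P2ry12 -0.04 and -0.37 (SE 0.16 each). For GF minus SPF, 1 gene passed without SPF2152, without GF532 or with no filter on low counts; for acetate minus GF, 1, 2 and 1 passed without GF529, GF532 and GFA521.

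By camera the disease-associated list differed for GF minus SPF (median log2 0.29, adjusted p = 0.023, 0.95 with an estimated correlation), and had 0.76 without SPF2152, 0.056 without wild-type SPF 4, 0.25 without GF529 and 0.24 without GF526. Proliferation genes (0.42, 0.026, 0.95 with an estimated correlation) had 0.056 to 0.16 without any single one of wild-type SPF 2, 3 and 4, SPF2140, SPF2152, GF529, GF526 and GF527. For acetate minus GF, MHC class I genes (0.27, 0.014, 0.79 with an estimated correlation) had 0.33, 0.22, 0.082, 0.12 and 0.1 without GF532, GF531, GFA523, GFA524 and GFA522, and ribosomal proteins (0.33, 3.4e-11) had 0.79 with an estimated correlation.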

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

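The tests on colony background, library size, time of day, low-complexity libraries and SPF2152 were chosen only after the result was seen. The glucocorticoid list was written after other genes of its pattern had been seen and before its own values were tested, and the sample splits were set beforehand.

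Nnt, Wdfy1 and Gpr137b were called higher than SPF in GF of whole brain, cortex and wild-type hippocampus and with acetate in cortex and wild-type hippocampus, while in 5xFAD hippocampus the folds had the same direction (log2 0.63, 0.75 and 0.57 in GF, 0.70, 0.57 and 1.20 with acetate) but only Gpr137b with acetate passed (adjusted p = 0.051, 0.11 and 0.18, and 0.13, 0.55 and 0.011). Library size does not account for this, since mean total counts differed by at most log2 0.19 from SPF, below the smallest fold of these genes minus 2 SE in each wild-type comparison (0.47 at least). An inherited difference between the SPF and germ-free colonies could give such a pattern: 25% of the genes called in cortex acetate against SPF (13 of 52) and 42.9% in wild-type hippocampus had another called gene among their nearest tested neighbours, where random genes gave 0 to 11.5% and 0 to 9.5%. Between acetate and GF, both germ-free, hippocampus lay inside the random range (9.5%, 0 to 11.9%) and cortex above it (20.5%, 4.1 to 15.8%). Ide, another substrain gene, was lower in cortex GF and acetate (log2 -0.66 and -0.67, adjusted p = 0.011 and 0.022), and with similar folds did not pass in wild-type (-0.63 and -0.70, 0.075 each) or 5xFAD hippocampus (-0.48 and -0.53, 0.18 and 0.29), nor in whole brain (-0.30, 0.48). Whether the colonies differ is not given by the labels, so colony background and germ-free rearing cannot be told apart.

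Zbtb16, Pik3ip1 and Hif3a were called higher in GF and lower again with acetate in cortex, and Per1 and Pik3ip1 in wild-type hippocampus, while Ddit4 was called in whole brain but not in cortex acetate against GF (log2 -2.57, adjusted p = 0.47), and Pik3ip1 not in whole brain (0.28, 0.81). A glucocorticoid response in GF mice may be one reason. Its list moved as predicted in 4 of 5 comparisons by fry before adjustment (adjusted p = 0.053, other 0.45). Those within a region share GF libraries, which favours opposite moves, and regions share mice. The list had median log2 -0.15 in whole brain, against fry's direction, and its Fkbp5 is among the largest cortex falls, so it is not independent evidence. Another time of day at collection would move the clock phases apart in opposite ways in GF against SPF and acetate against GF, and no such reversal was seen (log2 -0.33 and -0.04 in cortex, -0.10 and -0.49 in hippocampus, 0.49 being the largest in size), but SE over libraries of 0.33 to 0.48 leave it open. Low-complexity hippocampus libraries do not account for the pattern, as the median of the seen genes without them was log2 -4 in acetate against GF, against -2.72 with them.

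The 5xFAD library SPF2152 sits at 0.2 on the scale of the disease-associated list from SPF wild type (0) to the other SPF 5xFAD libraries (1). Low depth does not account for this at 17.8 M counts, nor does a swap with a wild-type SPF hippocampus library, the highest of which stands at 0.02. A wild-type sample under a 5xFAD label would lie at 0, and 0.2 is 11 SD above the SPF wild-type libraries by their own spread but 2.4 SD by the spread within all hippocampus groups. Whether wild-type and 5xFAD cells were mixed in one library App cannot decide, as wild type outside SPF reached 218.4 CPM. App was 191.4 CPM (SPF wild type 138.1 to 159.7, other SPF 5xFAD 199.1 to 218.8). It stood at 0.68, list genes in CPM at a median of 0.04, 3.8 SD apart by the SPF spread and 2 by the wider. The wider spread was chosen after both were seen, and the narrower would exclude a wild-type sample. So that, a mixture or a weak response in that mouse, which was not tested, cannot be told apart.

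Other splits of the samples asked whether another grouping gives as many calls. None of those run did for whole brain (226 calls, highest other split 1), cortex (259 and 1 for GF against SPF, 147 and 2 for acetate against GF, 55 and 9 for acetate against SPF) and wild-type hippocampus (124 and 2, 84 and 75, 21 and 0, in the same order). Nor did any for 5xFAD hippocampus (311 and 82, 14 and 0, 9 and 0), for 5xFAD against wild type in SPF (97 and 67) and acetate (428 and 5), and between regions (2086 and 1). In each only 1 split, the real one, reached this. The split with 75 calls puts GFA518 with the GF libraries, and those with 82 and 67 put SPF2152 with GF or with wild type, so they point to a structure of the samples. For GF 5xFAD against wild type the 10 splits are too few (129 and 0). The interactions had 0 calls, a count that every split reaches (all 40 for each 5xFAD interaction and all 35 for each region interaction, highest others 481 and 0, and 1 and 0), so the splits decide nothing there. The split with 481 calls exchanges wild-type GF and SPF libraries, so it shows a structure of the samples.

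A value was marked when 1 library lay far outside the others of its group. Of 255 such tests 18 were marked, where about 1 in 20 is reached by chance. Erythroid genes were high in whole-brain GF library 1 (mean log2(CPM + 1) 0.211, others at most 0.06), cortex SPF1 (0.614, 0.069), cortex GF529 (1.92, 0.297) and wild-type hippocampus SPF3 (2.895, 0.287). Choroid plexus genes were high in whole-brain GF library 1 (0.48, 0.087), cortex GFA524 (0.736, 0.083), wild-type hippocampus SPF2 (1.576, 0.36) and 5xFAD hippocampus GFA522 (1.212, 0.168). Neutrophil genes were high in cortex GFA524 (1.551, 0.952) and SPF2153 (4.194, 0.871). Endothelial genes were high in cortex GF529 (1.63, 1.442), oligodendrocyte precursor genes in cortex GFA525 (0.245, 0.087), and disease-associated genes in cortex SPF1 (5.81, 5.741). Genes detected were many in cortex SPF2 (19880, others at most 19140) and few in SPF2142 (17420, others at least 19370) and hippocampus GFA518 (16610, 19140). Trem2 stood at 1590 CPM in whole-brain GF library 2 (others at most 1476) and Sdha at 328.8 CPM in cortex SPF1 (266.3).

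Lists were marked where an interaction had a camera call. In the 5xFAD effect these were disease-associated genes (adjusted p = 0.023) and proliferation (0.026) for GF minus SPF, and MHC class I (0.014) and ribosomal proteins (3.4e-11) for acetate minus GF. In the region effect they were disease-associated genes (0.0018), phagocytosis (0.049) and unfolded protein genes (0.049) for GF minus SPF, and complex I (0.00069) and complex IV (0.021) for acetate minus GF. With an estimated correlation none passed (0.95, 0.79, 0.81 and 0.84).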

How the results depend on the processing

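Groups of 3 to 5 mice, libraries from 5.74 M counts and bulk cells limit what these counts show, and low genes of shallow libraries lack precision. Comparisons, filters, the lists named in processing and the other alternatives were set before the data were examined. Chosen after seeing the data were 4 fits, which leave out doubted or shallow libraries, and the substrain, glucocorticoid and clock phase lists with their tests. A Y-linked covariate was not run in whole brain, where Ddx3y had 0 CPM throughout. Where a count moved, the cause was not tested.

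Numbers of calls by DESeq2 were higher throughout: whole brain 638, cortex GF against SPF 627, acetate against GF 467 and acetate against SPF 136, the same in wild-type hippocampus 442, 376 and 87, in 5xFAD hippocampus 609, 151 and 90, for 5xFAD against wild type 317 in SPF, 429 in GF and 771 with acetate, 15 and 7 in the 5xFAD interactions (GF minus SPF, acetate minus GF), 3182 between regions, and 13 and 2 in the region interactions. In a fit of only the 2 groups, cortex gave 153 (GF against SPF) and 316 (acetate against GF), wild-type hippocampus 34, 0 and 11, 5xFAD hippocampus 121 (acetate against GF) and 2 (acetate against SPF), and SPF 5xFAD against wild type 10. With no filter, cortex acetate against SPF gave 85, 5xFAD acetate against GF 30, the 5xFAD interaction GF minus SPF 1, and the region interactions 22 and 17. With a mean of at least 5 CPM, 5xFAD acetate gave 46 against GF and 5 against SPF. With the mean level of Y-linked genes as a covariate, 5xFAD hippocampus GF against SPF gave 203, acetate against SPF 5 and GF 5xFAD against wild type 80, and other counts in cortex and hippocampus stayed within 1.5-fold. RLE size factors moved no count by more than 1.5-fold.

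In whole brain a replicate block, pairing mice by the number in their name, gave 51 calls, 34 higher and 17 lower, 48 of them shared. Residuals of same-number pairs had r = -0.003, -0.037 and -0.009.

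Without SPF2152, SPF 5xFAD against wild type gave 327, GF 5xFAD against wild type 199 and the interaction GF minus SPF 1. Without SPF2152, GFA518 and GF530, wild-type acetate against GF gave 127, 5xFAD GF against SPF 477, acetate against GF 61, acetate against SPF 38, SPF 5xFAD against wild type 457 and the interaction 1. Without the 2 shallow libraries, wild-type GF against SPF gave 78, 5xFAD acetate 23 against GF and 2 against SPF, and SPF 5xFAD against wild type 21. Without animals GFA518 and GF530, regions gave 1356 and the region interaction acetate minus GF 1.

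With each library left out in turn, the lowest and highest counts were 83 and 242 in whole brain, 124 and 379, 23 and 166, and 25 and 55 in cortex (order as above), 25 and 109, 29 and 130, and 12 and 22 in wild-type hippocampus, and 107 and 319, 2 and 38, and 1 and 10 in 5xFAD hippocampus. They were 26 and 327, 31 and 123, and 252 and 379 for 5xFAD against wild type in SPF, GF and acetate, 0 and 1, and 0 and 2 in the 5xFAD interactions, 1242 and 2061 between regions, and 0 and 1 in both region interactions.

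No called gene changed sign in any setting. A list passed camera against the direction camera gave with the reported fit in 7 results, none of which passed there: ribosomal proteins in cortex GF against SPF without SPF1 (log2 -0.09, adjusted p = 0.03, up to 0.14 without another library), disease-associated genes in 5xFAD GF against SPF without SPF2152 (-0.23, 0.0032, in each of the 2 settings that omit it, up to 0.11 without SPF2142) and without SPF2152, GFA518 and GF530 (-0.22, 0.0058), ribosomal proteins in the 5xFAD interaction GF minus SPF without the shallow libraries (0.14, 0.035), and immediate-early genes in the region interaction acetate minus GF without GF530 (0.27, 0.00018, down to -0.29 without GF532) and without GFA518 and GF530 (0.32, 0.00019). Over all settings, 10343 gene results stayed the same, 1484 became weaker and 74 stronger, and of list results 9608 stayed the same, 432 became weaker and 314 stronger.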

Other observations

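In SPF 5xFAD against wild type, complex III (9 genes, median log2 0.03), histone acetyltransferases and deacetylases (27 genes, 0.03) and LXR targets (13 genes, 1 higher, -0.13) had camera adjusted p = 0.58 each, and Y-linked genes (4, -0.01) 0.79. In cortex GF against SPF, complex III (0.08) and histone acetyltransferases and deacetylases (0.08) had 0.65, LXR targets (12 genes, 1 higher, -0.10) 0.89, Y-linked genes (0.04) 0.88 and clock genes (16, 1 higher, 0.01) 0.82.

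Of markers of other cells in SPF 5xFAD against wild type, border macrophages had a camera call (median log2 1.11, adjusted p = 0.014, 0.11 with an estimated correlation), and these had none: B cells (3 genes, median log2 -0.14, adjusted p = 0.33), erythroid cells (3, -3.12, 0.58), neurons (5, -0.39, 0.25), astrocytes (5, 0.97, 0.58), oligodendrocytes (7, -0.14, 0.29), pericytes and smooth muscle (4, -1.74, 0.3), choroid plexus (3, -4.06, 0.68), endothelial cells (7, 0.31, 0.59) and monocytes (5, 0.32, 0.29). Lists with too few tested genes are given as group means of log2(CPM + 1). X inactivation had 3.73 and 4.28 in whole-brain GF and SPF and at most 0.47 elsewhere. Oligodendrocyte precursors had 0.08 to 0.4, neutrophils 0.85 to 1.88, and transgene homologues 5.16 in SPF 5xFAD against 5.1 in SPF wild type of hippocampus.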
